A study of Mus musculus with 6 samples.

How the data were processed

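The data are 6 RNA-seq libraries of mouse CD8+ T cells activated in vitro and collected on day 2, 3 labelled Nae1T-KO and 3 labelled Nae1WT. Per the labels' protocols, total RNA was taken from frozen cell pellets, messenger RNA was captured on poly-T beads, and complementary DNA was made with random hexamers. Per the submitters' processing notes, the processing involved bcl2fastq, HISAT2, DESeq2 1.42.0 and the mouse genome build mm10. The read counter, its gene annotation, its use of strand and its treatment of reads that match several genes are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies may therefore be shared between genes. Of the 122 genes named by the fixed rule, 37 overlap another measured gene by their RefSeq spans. Overlap with RefSeq genes absent from the deposited data was not counted.

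The authors deposited 1 table of normalized counts, a signal that is never negative, with 18288 gene symbols and 1 column per library. The deposited signal has no stated unit. In each column every value was a whole multiple of 1 step, the value of 1 read, with a tolerance of 0.001 of a read for 100% of values. The steps matched the inverse of DESeq2's size factors computed from the recovered reads, with a ratio of 1 in each library. For Nae1T-KO replicate 3 the step was so close to 1 that recovery is less certain from the values alone, and its reads were recovered in the same way. Recovered totals were about 15628300 to 25444700 reads per library. The table appeared to leave out genes with few reads, since the smallest sum of a gene over the 6 libraries was 11 reads. The design had been fixed for raw counts with the edgeR quasi-likelihood test. Because the deposited values are normalized counts, the test that fits the unit was used instead, as the design had provided, and count tests on recovered reads became alternatives. For the same reason the list tests ran on log2(normalized count + 1) rather than log2 CPM, which became an alternative.

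Genes were tested on log2(normalized count + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust variance estimation, for group alone. Fold changes are on this log2 scale, which understates the change of low genes. A gene was tested if its normalized count was at least 10 in at least 3 libraries, which left 13819. Tests were two-sided, and Benjamini-Hochberg adjusted p-values under 0.05 over all tested genes were called. All symbols (18288) matched the RefSeq table of GRCm38.p6, from which coordinates were taken.

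Gene lists (42) and the rule for naming genes were fixed before the data were examined. The rule names Nae1 and Uba3, the 10 genes with the largest increase and the 10 with the largest decrease. These 10 and 10 were taken from called genes with a mean of at least 5 CPM and no overlap between groups. It also names up to 3 called members of each list, those with the largest change at a mean of at least 5 CPM. A further 16 genes are named regardless of their test. Predicted and clone-based genes, antigen receptor segments, mitochondrially encoded genes and Y-linked genes were left out of the largest changes. Lists with at least 5 tested members, 41 of them, were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry beside it. The list of gamma-delta T and NK cell markers had too few tested members. Symbols of mitochondrial genes were translated to the RefSeq names of the table. With the estimated correlation 0 of the 41 lists passed, and fry's directional p called 6, of which 5 were among the 11 called by camera. Median, mean and tests differed in sign for the effector molecule, inhibitory receptor, JAK-STAT, NF-kB and trafficking lists.

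The fits were tested on simulated counts with the real means, dispersions and library sizes and 200 changed genes. In the simulated comparison of Nae1T-KO with Nae1WT over 13612 genes, limma recovered 53.8% of genes changed 1.5-fold, 93.9% of those changed 2-fold and 90.9% of those changed 4-fold, with 10 false calls among 167. Camera called 5 of 5 shifted random lists and 0 of 35 unshifted ones. Genes were simulated independently of each other, so this does not show camera's rate of false calls for lists of correlated genes.

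Alternatives were upper-quartile, total-count and TMM scaling, no filter and a stricter filter (a CPM of at least 5 in at least 3 libraries), pseudocounts of 0.5 and 5, leaving out each library, a replicate block by the number in the titles or, on 4 libraries, in the library names, edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered reads, an adjusted p under 0.01, a test against a 1.5-fold change, and sex as a covariate. Sex was read from Xist and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. TMM scaling, the pseudocounts, edgeR with TMM factors, camera on log2 CPM and the sex covariate were added after seeing the data. On the recovered reads edgeR with TMM factors called 1798 genes of 13823, 941 higher and 857 lower. Replicates were compared before use, and every pair of libraries differed by more than sampling noise, with 32.6% to 57.5% of genes at p under 0.05 in a chi-square test of the reads. Figures were drawn with matplotlib 3.10.9.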

Results

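Gene expression was measured by RNA sequencing in mouse CD8+ T cells, the cytotoxic arm of the T cell compartment, that had been activated in culture and harvested on day 2. The labels name 2 groups, Nae1T-KO and Nae1WT, with 3 biological replicates each. Nae1 encodes the regulatory subunit of the NEDD8-activating enzyme, which works as a heterodimer with UBA3 and starts the attachment of the ubiquitin-like protein NEDD8 to cullins and other targets. The comparison asks which transcripts differ between activated CD8+ T cells of the 2 genotypes. Values are read counts divided by 1 size factor per library, called normalized counts here. The 3 Nae1T-KO libraries held about 16995000, 20849500 and 18967400 reads assigned to genes and the 3 Nae1WT libraries about 15628300, 18992000 and 25444700. The labels do not say whether the replicates came from separate mice, so p-values measure the spread between these samples.

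Nae1 was lower in every Nae1T-KO library. Its normalized count was 390.3, 338 and 367 in the Nae1T-KO libraries and 1601, 1806 and 1882 in the Nae1WT libraries, which gave 365 ± 26.4 (SD, n = 3) against 1763 ± 145 (SD, n = 3). The log2 fold change was -2.27 with a standard error of 0.09 (limma, adjusted p = 5.03e-07), a level 4.82-fold lower in Nae1T-KO. Behind these values stood 349 to 383 reads per Nae1T-KO library and 1304 to 2472 reads per Nae1WT library. The gene lies on chromosome 8 from 104511028 to 104534656 in GRCm38 (mm10). The labels do not say which part of Nae1 was deleted, and gene-level counts do not show which exons the remaining reads came from. Uba3, the partner subunit, had 2610 ± 216 (SD, n = 3) normalized counts in Nae1T-KO and 2565 ± 122 (SD, n = 3) in Nae1WT, a log2 fold change of 0.02 with a 95% interval of -0.15 to 0.20 (limma, adjusted p = 0.884). Its sign changed without Nae1T-KO replicate 1 (-0.0108), Nae1T-KO replicate 3 (-0.0150) or Nae1WT replicate 1 (-0.00587).

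**Figure D1:**
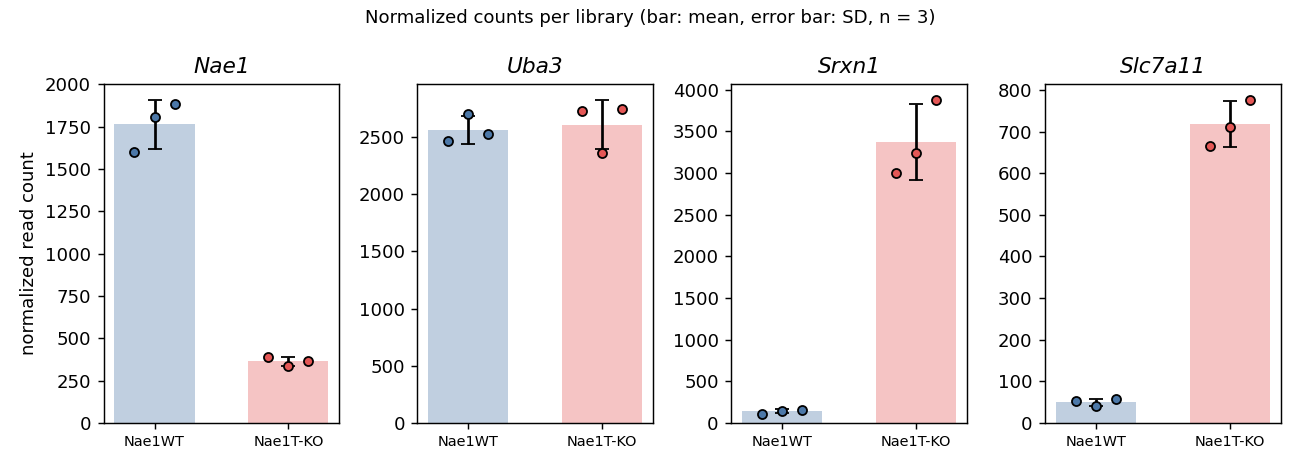
Normalized read counts (vertical axis, from 0) of Nae1, Uba3, Srxn1 and Slc7a11 in the Nae1WT and Nae1T-KO libraries. Points are libraries, bars are means and error bars are the SD of 3 libraries. Nae1 lies between 338 and 390.3 in Nae1T-KO and between 1601 and 1882 in Nae1WT, and Srxn1 and Slc7a11 are higher in each Nae1T-KO library than in any Nae1WT library.

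Of 13819 genes tested, 1757 differed between the groups (limma, adjusted p under 0.05), 903 higher and 854 lower in Nae1T-KO. The higher genes included more large changes, with 199 at least 2-fold higher and 84 at least 2-fold lower. With scaling to total counts instead of the deposited size factors, 1176 were higher and 622 lower. The groups did not overlap for 33.7% of all tested genes, where chance alone gives 10%. The count depended on single libraries: it was 1034 without Nae1T-KO replicate 2, 844 without Nae1WT replicate 2 and 954 without Nae1WT replicate 3. The libraries also differed in sex, which the labels do not give. Xist, the transcript of the inactive X chromosome, had 14225, 16521 and 20518 normalized counts in Nae1T-KO replicates 1 and 2 and Nae1WT replicate 3, and at most 4.04 in the other 3, which alone expressed the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. With sex as a covariate, a fit added after seeing the data, 1540 genes differed, 772 higher and 768 lower, and 1372 of the 1757 were called again in the same direction.

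Among the genes with the largest increases by the fixed rule were Srxn1, which encodes sulfiredoxin and ranked highest, and Slc7a11, the cystine transporter subunit. Srxn1 rose from 138 ± 23.3 (SD, n = 3) to 3373 ± 453 (SD, n = 3) normalized counts, a log2 fold change of 4.61 ± 0.14 (SE, adjusted p = 1.41e-07), and Slc7a11 from 49.5 ± 8.88 (SD, n = 3) to 718 ± 55.2 (SD, n = 3), a log2 fold change of 3.85 ± 0.15 (SE, adjusted p = 5.03e-07). In GRCm38 Srxn1 lies on chromosome 2 from 152105524 to 152111376 and Slc7a11 on chromosome 3 from 50364936 to 50499087. The other genes among the 10 with the largest increase were Ptprn at 3.87, Inhba, which encodes an activin subunit, at 3.80, Nqo1 at 3.03, the chemokine gene Cxcl10 at 3.01, the cytokine gene Il3 at 2.64, Ramp3 at 2.55, Sdcbp2 at 2.34 and Trim66 at 2.24 (log2 fold changes). After Nae1 itself, the largest decreases were in Samd3 at -1.72, Nrgn at -1.56, Spp1, which encodes osteopontin, at -1.45, Lipg at -1.42, the interleukin 18 receptor gene Il18r1 at -1.40, Sh3bgrl at -1.33, Sh2d1a, which encodes the SLAM-associated adaptor SAP, at -1.31, Ly6c2 at -1.28 and Tex15 at -1.25. Adjusted p was between 1.41e-07 and 0.0127 for these 20 genes. Spp1 and Ramp3 each kept their call in 19 of 20 alternatives, with the highest adjusted p at 0.244 and 0.0556. The call for Inhba ended in limma-voom, with either replicate block and without Nae1WT replicate 2 (log2 fold change 3.95, adjusted p = 0.0544, and 8.03e-09 to 0.0913 over the alternatives), and that for Lipg with the replicate block on 4 libraries and without Nae1T-KO replicate 2 (-1.48, adjusted p = 0.0565) or Nae1WT replicate 2 (-1.42, adjusted p = 0.0600), with 1.20e-08 to 0.0600 over the alternatives.

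Most genes listed as targets of NRF2, the transcription factor of the antioxidant response, were higher in Nae1T-KO. Of 25 measured members, 18 were higher, 0 lower and 7 not past the threshold, with the same 18 and 0 when adjusted over the list alone. The list's median log2 fold change was 0.84, and camera called it with adjusted p = 9.46e-15, against adjusted p = 0.192 with an estimated correlation and fry adjusted p = 0.000343. Besides Srxn1 and Slc7a11, Nqo1, a quinone reductase, went from 20.7 ± 5.72 (SD, n = 3) to 173 ± 12.2 (SD, n = 3) normalized counts. Nqo1 lies on chromosome 8 from 107388225 to 107403205, within 10 Mb of Nae1. Nfe2l2, which encodes NRF2 itself, had 724 normalized counts in Nae1T-KO and 636 in Nae1WT, a log2 fold change of 0.19 with a 95% interval of 0.02 to 0.36 (adjusted p = 0.139). Between libraries of the same sex the list's median log2 difference was 0.76 to 0.89 over the 4 possible pairs.

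**Figure D2:**
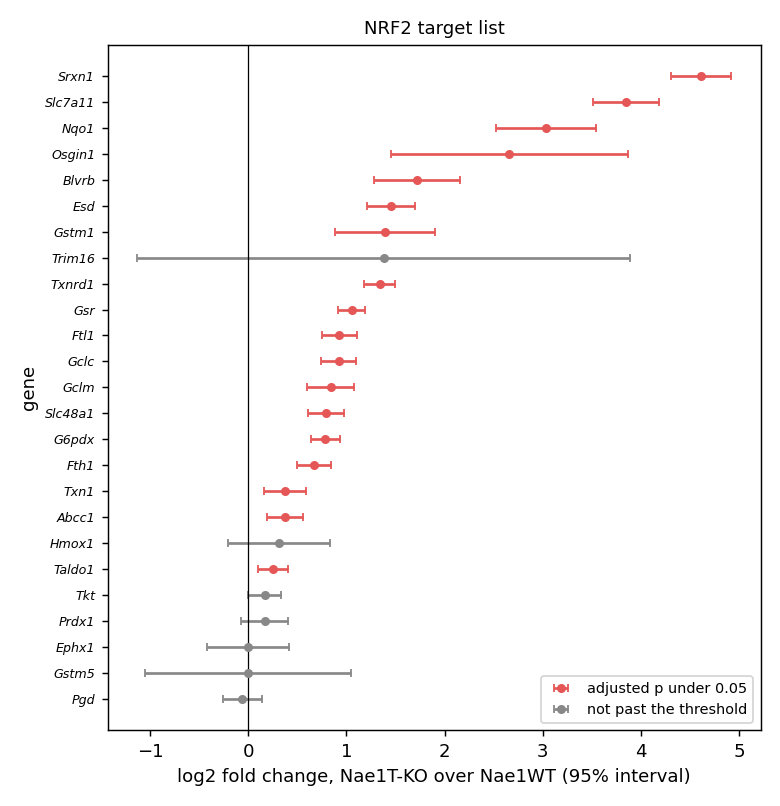
Log2 fold change of Nae1T-KO over Nae1WT (horizontal axis) for the 25 measured NRF2 target genes (vertical axis), with 95% intervals from limma on 3 and 3 libraries. Red points passed adjusted p under 0.05 and grey points did not. The 18 red points all lie above 0, up to 4.61 for Srxn1.

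Some interferon-stimulated genes were also higher in Nae1T-KO. Of 51 measured, 23 were higher, 0 lower and 28 not past the threshold, and 27 were higher and 2 lower when adjusted over the list alone. The median log2 fold change was 0.51 (camera, adjusted p = 1.93e-09, against adjusted p = 0.498 with an estimated correlation and fry adjusted p = 0.0283). Cxcl10 rose from 39.5 ± 10.7 (SD, n = 3) to 319 ± 41.2 (SD, n = 3) normalized counts. Oasl2, of the oligoadenylate synthetase family, had a log2 fold change of 1.47 ± 0.25 (SE, adjusted p = 0.00538) and Irf7, an interferon-induced transcription factor, one of 1.34 ± 0.25 (SE, adjusted p = 0.00838). Between libraries of the same sex the median log2 difference of the list was 0.26 to 0.66. Markers of myeloid and dendritic cells moved the same way at low levels. The 13 such markers in the table summed to 235, 352 and 260 normalized counts in the Nae1T-KO libraries and to 172, 97.2 and 133 in the Nae1WT libraries. Camera called this list higher over its 6 tested members (adjusted p = 0.00916, against adjusted p = 0.812 with an estimated correlation and fry adjusted p = 0.148). Its only member past the threshold over all genes was Xcr1, named after its values were seen, with a log2 fold change of 1.75 (adjusted p = 0.0350), while 4 were higher and 0 lower when adjusted over the list alone. B cell markers summed to 844, 1963 and 860 in Nae1T-KO and 650, 563 and 1011 in Nae1WT, and erythroid markers to 511, 2155 and 294 against 177, 361 and 844, both highest in Nae1T-KO replicate 2. Markers of gamma-delta T and NK cells summed to 139, 96.9 and 159.5 in Nae1T-KO and 138, 195 and 187 in Nae1WT. CD4 T cell markers summed to 1750.3, 1697 and 1637 in Nae1T-KO and 1276, 1311 and 1403 in Nae1WT, higher in each Nae1T-KO library than in any Nae1WT library. The largest gain among them was in the cytokine gene Il13, with 669, 352 and 245 normalized counts in Nae1T-KO against 83.5, 160 and 203 in Nae1WT. Cd4 itself overlapped between the groups, with 20.1, 118 and 72.7 against 119, 20.9 and 42.6. Both genes were named after their values were seen. Limma called 0 of 12 tested B cell markers and 0 of 6 erythroid markers, with 4 and 0 at an unadjusted p under 0.05. On the recovered reads DESeq2 called 3 and 0, and edgeR and limma-voom 0 and 0. Camera gave the B cell list adjusted p = 0.125 and the erythroid list adjusted p = 0.362. The B cell list passed, as higher, without Nae1T-KO replicate 1 (adjusted p = 0.00998) or Nae1WT replicate 3 (adjusted p = 0.0175), with 0.00998 to 0.883 over the alternatives.

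Most p53 targets that passed the test were higher in Nae1T-KO, and most DNA replication genes that passed were lower. Among 33 measured p53 targets, 11 were higher, 1 was lower and 21 were not past the threshold, with 12 higher and 3 lower when adjusted over the list alone (median log2 fold change 0.18, camera adjusted p = 0.000620, against adjusted p = 0.498 with an estimated correlation and fry adjusted p = 0.0213). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose by a log2 fold change of 0.85 ± 0.08 (SE, adjusted p = 0.000425), Plk3 by 0.88 ± 0.11 (SE, adjusted p = 0.00114) and Perp by 0.82 ± 0.10 (SE, adjusted p = 0.00116). Of 54 DNA replication genes, 13 were lower, 1 was higher and 40 did not pass, with 25 lower and 2 higher when adjusted over the list alone (median log2 fold change -0.18, camera adjusted p = 1.55e-07, against adjusted p = 0.668 with an estimated correlation and fry adjusted p = 0.0234). The clamp loader gene Rfc4 fell by 0.73 on the log2 scale, the polymerase alpha gene Pola1 by 0.52 and the origin recognition gene Orc5 by 0.50. DNA damage response genes had 8 lower, 0 higher and 28 not past the threshold of 36, with 10 lower and 0 higher when adjusted over the list alone (camera adjusted p = 0.00210, against adjusted p = 0.845 with an estimated correlation and fry adjusted p = 0.106), among them Brca2 at -0.59, Fancb at -0.55 and the checkpoint kinase gene Atr at -0.52. Replication histone genes had 4 lower, 0 higher and 13 not past the threshold of 17, and the same 4 when adjusted over the list alone (camera adjusted p = 0.00218, against adjusted p = 0.845 with an estimated correlation and fry adjusted p = 0.175). The histone call ended in fry, under the stricter filter (adjusted p = 0.0681) and with the replicate block on 4 libraries (adjusted p = 0.0555), with 5.63e-06 to 0.845 over the alternatives. One of the 4, H1f0 at -0.95, encodes a replacement linker histone. The libraries were made by capture on poly-T beads, so counts of this list may not follow histone messenger RNA that lacks a poly(A) tail. The histone list's median log2 fold change between the groups was -0.51. Within Nae1WT its median was 0.48 and 0.63 higher in replicates 1 and 2 than in replicate 3, a spread of similar size. Between libraries of the same sex it was -0.52 to -0.25. The G2/M list had 8 of 58 higher and 6 lower, and 10 higher and 10 lower when adjusted over the list alone (camera adjusted p = 0.620), with Ube2c at 0.62 and Incenp at 0.50. G1/S regulators had 3 of 25 higher and 2 lower, and 8 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.362). Mki67, a proliferation marker, had 0.04 (limma, adjusted p = 0.806), and -0.00312 without Nae1WT replicate 3.

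Cytokine and effector genes changed in both directions. Among 33 effector molecules, 4 were higher, 5 lower and 24 not past the threshold, with 9 and 9 when adjusted over the list alone (camera adjusted p = 0.998). Il2 rose from 646 ± 77.7 (SD, n = 3) to 1957 ± 577 (SD, n = 3) normalized counts, a log2 fold change of 1.56 ± 0.22 (SE, adjusted p = 0.00715), and Il3 from 227 ± 94.1 (SD, n = 3) to 1330.4 ± 69.6 (SD, n = 3). Lta, which encodes lymphotoxin alpha, fell by 0.84 on the log2 scale, and Prf1, which encodes perforin, by 0.38 (adjusted p = 0.0131), a call that ended with the replicate block on 4 libraries and without Nae1WT replicate 2 (-0.33, adjusted p = 0.0646, and 0.00227 to 0.125 over the alternatives). Ifng had 13188 ± 2561 (SD, n = 3) normalized counts in Nae1T-KO and 25629 ± 7083 (SD, n = 3) in Nae1WT and did not pass (log2 fold change -0.93, adjusted p = 0.0674), although it did without Nae1WT replicate 1 (-1.19, adjusted p = 0.00359), under the stricter filter, with the replicate block on 4 libraries and in DESeq2 on the recovered reads, with 0.00359 to 0.193 over the alternatives. Gzmb, which encodes granzyme B, had a log2 fold change of -0.16 (95% interval -0.47 to 0.15, adjusted p = 0.486). Tnf had 0.28 (adjusted p = 0.0998) and passed without Nae1T-KO replicate 1 (0.40, adjusted p = 0.0307) and with sex as a covariate, with 0.0307 to 0.383 over the alternatives.

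Receptors and transcription factors that mark activation or memory states changed gene by gene. The early activation list had 9 of 33 members higher, 3 lower and 21 not past the threshold, with 14 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0352, against adjusted p = 0.498 with an estimated correlation and fry adjusted p = 0.0213). It lost its call without Nae1T-KO replicate 1 (adjusted p = 0.0615), without Nae1T-KO replicate 2 (adjusted p = 0.0630), under the stricter filter (adjusted p = 0.0681), with the replicate block on 4 libraries (adjusted p = 0.0932) and with sex as a covariate (adjusted p = 0.0558), with 0.0213 to 0.498 over the alternatives. Fosl2 and Dusp5 each rose by 0.86 on the log2 scale, and Egr3 fell by 0.92. Inhibitory receptors had 4 of 19 higher and 4 lower, the same when adjusted over the list alone (camera adjusted p = 0.926). Havcr2, which encodes TIM-3, had a log2 fold change of 1.32 and Tigit one of 0.97, while the activating receptor gene Klrk1 on the same list had -0.69. Effector transcription factors had 2 of 24 higher and 3 lower, and 3 and 3 when adjusted over the list alone (camera adjusted p = 0.806), with Eomes at -0.86 and Runx1 at 0.61. Naive and memory genes had 7 of 33 higher and 4 lower, and 10 and 4 when adjusted over the list alone (camera adjusted p = 0.180), with Satb1 at 0.99, Ly6c2 at -1.28 and Dapl1 at -1.01. This list passed, as higher, without Nae1T-KO replicate 1 (adjusted p = 0.00998) or Nae1WT replicate 1 (adjusted p = 0.0341), with 0.00998 to 0.883 over the alternatives. In limma Tbx21 had -0.08 (adjusted p = 0.547), Tcf7 0.05 (adjusted p = 0.751), Myc 0.15 (adjusted p = 0.141), Il2ra 0.12 (adjusted p = 0.592) and Cd8a -0.09 (adjusted p = 0.557). Without Nae1T-KO replicate 1 the sign of Il2ra (-0.0373) and of Cd8a (0.00295) changed. Trafficking receptors had 3 of 24 higher and 4 lower, and 3 and 6 when adjusted over the list alone (camera adjusted p = 0.685), with the integrin gene Itga4 at -0.83 and Cxcr3 at -0.78. CD8 T cell identity genes had 1 of 9 higher and 1 lower, the same when adjusted over the list alone (camera adjusted p = 0.408).

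Among metabolic groups, some genes of cholesterol synthesis were lower in Nae1T-KO. Of 25 measured, 7 were lower, 0 higher and 18 not past the threshold, and 14 were lower and 0 higher when adjusted over the list alone (median log2 fold change -0.28, camera adjusted p = 0.000342, against adjusted p = 0.883 with an estimated correlation and fry adjusted p = 0.171). Msmo1 fell by 0.61 and Lss, which encodes lanosterol synthase, by 0.60 on the log2 scale. Between libraries of the same sex the median log2 difference of the list was -0.53 to -0.08. The 13 protein-coding mitochondrial genes had been listed as a mark of RNA quality. They had 3 lower, 0 higher and 10 not past the threshold, and the same 3 when adjusted over the list alone (median log2 fold change -0.43, camera adjusted p = 0.00160, against adjusted p = 0.883 with an estimated correlation and fry adjusted p = 0.175), with ND3 at -0.81. Their median log2 difference was -0.50 and -0.48 in the pairs of libraries with Xist and 0.04 and -0.13 in the pairs with Y-linked transcripts. Nuclear genes of oxidative phosphorylation had 7 of 66 lower and 0 higher, and 5 lower when adjusted over the list alone (camera adjusted p = 0.0352, against adjusted p = 0.895 with an estimated correlation and fry adjusted p = 0.503). That call ended without Nae1T-KO replicate 2 (adjusted p = 0.482), Nae1WT replicate 2 (adjusted p = 0.329) or Nae1WT replicate 3 (adjusted p = 0.0555). It also ended in fry, with total-count scaling (adjusted p = 0.0606), under the stricter filter (adjusted p = 0.0622), with the replicate blocks (adjusted p = 0.0603 by title number and 0.126 on 4 libraries) and with sex as a covariate (adjusted p = 0.200), with 0.000465 to 0.895 over the alternatives. Glycolysis genes had 4 of 21 higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.200), with Ldhb at 0.69 and Aldoa at 0.45. It passed, as higher, without Nae1T-KO replicate 3 (adjusted p = 0.0182, and 0.0182 to 0.895 over the alternatives). Hypoxia-inducible factor targets had 2 of 22 higher and 2 lower (camera adjusted p = 0.620), with Ndrg1 at 0.80 and Narf at -0.98, and Hif1a had 0.35 (adjusted p = 0.0913), which passed without Nae1T-KO replicate 3 (0.48, adjusted p = 0.0110) and in DESeq2, with 0.0110 to 0.440 over the alternatives. The tricarboxylic acid cycle list had 2 of 21 lower, the one-carbon and serine list 3 of 20 lower, and both had 0 higher, with camera adjusted p = 0.274 and 0.180. For the hypoxia, tricarboxylic acid cycle and one-carbon lists the counts adjusted over the list alone were the same. Fatty acid synthesis had 0 of 16 called by limma, with 0 higher and 1 lower at an unadjusted p under 0.05 and 0 called by edgeR, DESeq2 or limma-voom (camera adjusted p = 0.0973). As a list it passed, as lower, without Nae1T-KO replicate 1 (adjusted p = 0.00540), without Nae1WT replicate 2 (adjusted p = 0.0287) and with sex as a covariate (adjusted p = 0.00648), with 0.00540 to 0.883 over the alternatives.

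The neddylation list had 2 of 24 members higher and 4 lower, Nae1 among them, and 2 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.125). It passed, as lower, without Nae1WT replicate 1 (adjusted p = 0.0445, and 0.0445 to 0.883 over the alternatives). Dcun1d3, which encodes a NEDD8 ligase cofactor, rose by 1.15 on the log2 scale, and Cops3, of the COP9 signalosome that removes NEDD8, fell by 0.48. Cullin-RING ligase genes had 4 of 37 higher and 3 lower, and 7 and 4 when adjusted over the list alone (camera adjusted p = 0.362), with Socs3 at 0.76, Socs2 at -1.17 and Crbn at -0.57. The cytokine and JAK-STAT list had 3 of 35 higher and 6 lower, and 7 and 7 when adjusted over the list alone (camera adjusted p = 0.998). T cell receptor signalling had 3 of 37 higher and 4 lower, the same when adjusted over the list alone (camera adjusted p = 0.620), with Themis at -0.69 and Cd3g at -0.51. NF-kB targets had 4 of 30 higher and 4 lower, and 7 and 5 when adjusted over the list alone (camera adjusted p = 0.620), with Map3k14 at 0.71 and Nfkbid at 0.64. Autophagy and lysosome genes had 7 of 33 higher and 1 lower, and 9 and 3 when adjusted over the list alone (camera adjusted p = 0.0542, fry adjusted p = 0.000507), with the autophagy genes Gabarapl1 at 0.62 and Ulk1 at 0.55. In camera this list passed with total-count scaling (adjusted p = 0.0452), with no filter (adjusted p = 0.0499) and without Nae1WT replicate 1 (adjusted p = 0.0445), with 0.000507 to 0.498 over the alternatives. Apoptosis genes had 6 of 28 higher and 1 lower, and 9 and 2 when adjusted over the list alone (camera adjusted p = 0.240). The members named by the fixed rule were Casp6 at 1.33, Bcl2l2 at 0.65 and Bbc3 at 0.65. The calls of Casp6 and Bbc3 held in 18 and 16 of 20 alternatives.

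The remaining lists did not pass camera on the 6 libraries. ATF4 and integrated stress response genes had 5 of 32 higher and 4 lower (adjusted p = 0.685), the same when adjusted over the list alone, with Sesn2 at 0.77 and Cth at -1.09. The unfolded protein response had 1 of 22 higher and 4 lower, and 1 and 5 when adjusted over the list alone (adjusted p = 0.240), with Sdf2l1 at -0.49. Heat shock genes had 3 of 17 higher and 0 lower, the same when adjusted over the list alone (adjusted p = 0.0748), and passed, as higher, with total-count scaling (adjusted p = 0.0452) and without Nae1T-KO replicate 2 (adjusted p = 0.0260) or Nae1WT replicate 2 (adjusted p = 0.0425), with 0.0260 to 0.883 over the alternatives. Nutrient transporters had 5 of 20 higher and 1 lower, and 7 and 2 when adjusted over the list alone (adjusted p = 0.180), with Slc16a10 at 0.77. Ribosome biogenesis had 2 of 50 higher and 0 lower, proteasome genes 4 of 43 higher and 0 lower, and 0 in either list when adjusted over the list alone (adjusted p = 0.620 and 0.685). Ribosomal protein genes had 1 of 62 higher and 1 lower, and 1 and 0 when adjusted over the list alone (adjusted p = 0.631), and passed, as lower, without Nae1T-KO replicate 3 (adjusted p = 0.0272, and 0.0272 to 0.964 over the alternatives). CD4 T cell markers had 0 of 10 called by limma, with 2 higher at an unadjusted p under 0.05 1 called by DESeq2 and 0 by edgeR or limma-voom (camera adjusted p = 0.198). Among the genes named here, Sh3bgrl, Plk3, Rfc4, Pola1, Orc5, Fancb, Atr, Incenp, Tigit, Eomes, Runx1, Itga4, Lss, Dcun1d3, Cops3, Socs2, Crbn, Map3k14, Gabarapl1, Casp6, Il2ra, Tcf7 and Hif1a share part of their span with another measured gene, so their counts may hold reads of both.

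**Figure D3:**
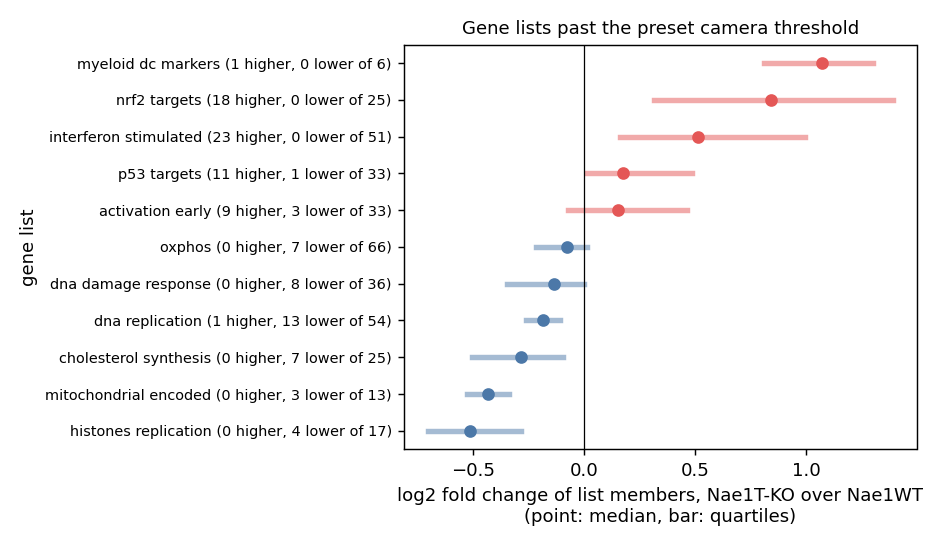
Median (points) and quartiles (bars) of the members' log2 fold changes, Nae1T-KO over Nae1WT (horizontal axis), for the 11 gene lists past adjusted p under 0.05 in camera with a preset correlation (vertical axis, with numbers of members called). Of the 11 medians, 5 lie above 0, up to 1.07, and 6 below 0, down to -0.51.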

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

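TMM scaling, the 2 pseudocounts, edgeR with TMM factors, camera on log2 CPM and the sex covariate were chosen after seeing the data; the other settings were planned. The Nae1 log2 fold change stayed past the threshold in all 20 alternatives, between -2.34 and -2.21. The number of differing genes stayed within 1.5 times of 1757 under every scaling, filter, pseudocount and count test and with the sex covariate. Without 1 library each it ranged from 844 to 1790, with 467 to 940 higher and 377 to 850 lower, and 10 to 14 lists were called. A replicate block by title number gave 968 genes, 513 higher and 455 lower. Same-numbered libraries deviated from their group means in opposite directions (r = -0.13, -0.18 and -0.27 across genes), and no library correlated best with its own number. Every same-numbered pair was of opposite sex, and r was 0.05 to 0.26 in pairs of the same sex. These values therefore cannot tell whether same-numbered libraries share a day or litter. A replicate block by the numbers in the library names, on 4 libraries, gave 253, 157 and 96, with fewer samples. An adjusted p under 0.01 gave 585 genes, 317 higher and 268 lower, and edgeR's test against a 1.5-fold change gave 99, 85 and 14, both by their stricter criteria. The stricter filter called 7 lists, estimated correlation 0 and fry 6, and the cause was not tested. Of the 12 named genes that did not pass, 4 changed sign without 1 library. Without 1 library Uba3 was -0.0150 to 0.0933 (also negative at -0.0108 and -0.00587), Il2ra -0.0373 to 0.243, Cd8a -0.163 to 0.00295 and Mki67 -0.00312 to 0.102. The cause was not tested. None of the 110 called named genes changed sign; 11 lost their call with the sex covariate, 19 with the block by title number, 67 with the block on 4 libraries and 8 to 29 without 1 library. With 3 libraries per group, 53.8% of simulated 1.5-fold changes were recovered, so small changes can be missed. The simulation made 167 calls, against 1757 in the real comparison, so the same adjusted p threshold was stricter in the simulation. The simulated share therefore cannot give the recovery rate of the real comparison, which was not measured.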

Other observations

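The tests of other cell types were chosen only after the levels of their markers had been seen, and the fit with a sex term was added after seeing the data. Of 15 mitochondrial transfer RNA genes tested, a group chosen after their values were seen and not tested as a list, 8 were lower in Nae1T-KO, 0 were higher and the others did not pass (limma, adjusted p under 0.05), with a median log2 fold change of -0.66. TrnG had 63.0 normalized counts in Nae1T-KO and 151 in Nae1WT, and TrnN had 319 and 544. Messenger RNA was captured on poly-T beads, so these counts need not measure mature transfer RNAs. The median log2 difference of the 15 genes was -1.06 to -0.41 over the 4 pairs of libraries of the same sex. Prdm1, which encodes the transcription factor BLIMP1 and was also chosen after its values were seen, had 60.8 against 12.5 normalized counts (log2 fold change 2.36, adjusted p = 0.00490). The ribosomal RNA transcript Rn18s-rs5 took 0.812% to 0.842% of reads in the 3 libraries with Xist and 1.46% to 2.09% in the 3 with Y-linked transcripts. Within 10 Mb of Nae1, 12 of 156 tested genes were called (7.69%), against 12.8% of the other 13662, an odds ratio of 0.569 (95% interval 0.287 to 1.03, Fisher's exact test, two-sided p = 0.0685).

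The real split of the 6 libraries gave 1757 genes, and the highest of the other splits gave 7. The real split was the 1 of 10 with that many, but 10 splits are too few for a share under 0.05. The split with 7 was the one that follows sex. A sex difference as the whole source of the group difference predicts fold changes near 0 once sex is in the model. The median ratio of the log2 fold change with the sex term to that without was 0.994 over the called genes (quartiles 0.937 and 1.05). Both groups held libraries of each sex, so a gene that follows sex alone spreads within its group and is rarely called. The ratio over called genes therefore cannot decide this. Over all tested genes, 1540 still differed between the groups with sex in the model, which argues against sex as the whole source.

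For the rise of NRF2 targets, the tables argue against unequal sex and against RNA from B, myeloid or erythroid cells as the explanation. Unequal sex would leave a median near 0 in some same-sex pair, and the smallest of 4 was 0.76. RNA from B, myeloid or erythroid cells would bring their abundant transcripts, and the largest gain of any of their markers (Hbb-bs, 439 against 184 normalized counts) was 0.00736 of the summed gain of the NRF2 targets. That gain came from Nae1T-KO replicate 2 (1051), while replicates 1 and 3 had 166 and 100, below the Nae1WT mean. Taken per Nae1T-KO library, the share was at most 0.0296. For more Nfe2l2 mRNA, a mark relative to the list's own median log2 fold change had been set beforehand. In these data the mark came to 0.42, so it depends on the rise it is used to judge. The log2 fold change of Nfe2l2 was 0.19 with an upper 95% bound of 0.36, below that mark. Targets need not rise in proportion to Nfe2l2 mRNA, so these values cannot decide whether a smaller rise contributed. The level of the NRF2 protein was not measured.

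For the rise of interferon-stimulated genes, the same tests left 2 technical explanations open. The smallest same-sex median was 0.2558, just under a bound of 0.2559 that was computed from the list's own median log2 fold change. By this test part of the rise may still go with sex. The smallest median came from Nae1T-KO replicate 1 against Nae1WT replicate 3. The other pair with Xist gave 0.61, and the pairs with Y-linked transcripts gave 0.43 and 0.66. The list kept its call in camera with sex as a covariate. The largest gain of a B cell, myeloid or erythroid marker was 0.0667 of the summed gain of the called interferon-stimulated genes, but 0.182 in the library where it was highest. The marker was Hbb-bs, with 1051 normalized counts in Nae1T-KO replicate 2. It had 166 and 100 in replicates 1 and 3, below the Nae1WT mean of 184. Myeloid markers were also higher, so RNA from these cells cannot be told apart from a change within the T cells. Markers of CD4 T cells were not part of this test. A response of the Nae1T-KO T cells themselves was not tested.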
